A study of Eubacterium limosum with 18 samples.

How the data were processed

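Eubacterium limosum KIST612, a strictly anaerobic acetogenic bacterium that can grow on sugars or on one-carbon gases, was grown on 1 of 3 substrates, namely glucose (20 mM), CO (101 kPa) or a mixture of H2 and CO2 (80% and 20%, 101 kPa). Total RNA was taken at mid-log and at early-stationary phase, and ribosomal RNA was depleted with a removal kit before Illumina library preparation, per the labels' protocols. The labels give 18 libraries in 6 groups of 3, each group being 1 substrate at 1 growth phase, and they number the replicates from 1 to 3. They do not state whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

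The deposited table holds RPKM, read numbers scaled by gene length and by sequencing depth, for 4586 rows named by locus tag, per the file headers, with 1 column for each of the 18 libraries. The number of per-sample columns left unused was 0. Bowtie, DESeq and edgeR are named in the submitters' processing notes without a role or a version. The genome build, the annotation and the counting rule are not given in the sources used here. The table holds no counts, and its low values were not whole multiples of the worth of 1 read, so the depth of each library is unknown and no counting interval is given. Summed RPKM ranged from 1037647 to 1585725 per library.

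Low values differed in kind between substrates. Among the 3 glucose mid-log libraries, 5 rows were at 0 in some replicates and above 0 in others, and among the 3 glucose early-stationary libraries 1 row was. The corresponding numbers were 428 and 580 for CO and 452 and 435 for H2/CO2, at mid-log and early-stationary phase. Glucose replicates therefore share nearly the same rows at 0, for a reason not given in the sources used here, and a value of 0 in glucose is not taken as measured absence of the transcript. In the comparisons of 1 group with another, a gene listed at 0 in all libraries of a group is reported as such, without a fold, while the fitted differences between phase effects include such genes.

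Values were analysed as log2(RPKM + 1). The 3662 rows with a mean of at least 5 RPKM over the 18 libraries were tested, and 924 were left out. One linear model with 6 group means was fitted over all 18 libraries with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, eBayes with a mean-variance trend). Contrasts were taken for 6 comparisons between substrates at the same phase, 3 comparisons of early-stationary against mid-log phase within a substrate, and 3 tests of whether the phase effect differed between substrates. P-values were two-sided and adjusted by Benjamini and Hochberg within each contrast. A gene was called at an adjusted p below 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(RPKM + 1) scale. Figures were drawn with matplotlib 3.10.9.

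The 153 pairs of libraries were compared and 0 held identical values. The script was tested on simulated data for CO against glucose at mid-log, with the real means and residual spread of the 3662 rows and 200 changed genes in each of 20 simulated sets. It recovered 27.1% of genes changed by 1 on the log2 scale, 63.6% of those changed by 1.5, 78.8% at 2 and 90.3% at 3, with a mean of 5.2 false calls. A true change of 1 lies at the threshold of the call, which limits its recovery. Noise was drawn independently for each library, while residuals of some real libraries were correlated, so 5.2 is not an error rate for these data.

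Neither the deposited table nor the labels pair the locus tags with gene names or products, and no annotation was used. The 32 gene lists written for this study, their set tests and the exclusion of ribosomal and transfer RNA rows were therefore not run. The comparisons, the tests, the gene lists, the rule for naming genes with its limit of 2 locus tags that rose and 2 that fell per comparison, and the alternatives below were chosen before the data were examined, except where stated. The rule takes the largest rises and falls among called genes whose 2 groups did not overlap, with at least 50 RPKM in the higher group; its condition on the annotated product could not be applied. Within the limit, each comparison names the largest rise and the largest fall. In the 3 substrate comparisons at mid-log and the 3 phase comparisons the most abundant member of the longest run in each direction was added, or the second largest change where the largest already lay in that run. This last choice was made after the data were seen. So were the response classes, the sums of RPKM over genes and the analysis of position.

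Runs are stretches of at least 4 consecutive tested genes called in the same direction, in the order of the table. That order follows the locus tag numbers except for a block of 70 tags with the highest numbers. Runs were counted again in 1000 shuffles of the gene order. Agreement between contrasts that share no library is given as Pearson's r across genes, with an interval of 95% from 1000 bootstrap resamples of blocks of 50 neighbouring tested genes. Genes are not independent replicates, so no p-value is attached. Intervals made in this way, here and for slopes along the gene order, hold the libraries fixed and leave out the spread between libraries. For CO and H2/CO2 against the same glucose libraries, 100 sets of unchanged groups were simulated to show what shared controls give.

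Other settings tried were a pseudocount of 0.1 or 10, no filter or a filter at 25 RPKM, median-ratio scaling or quantile normalization between libraries, a fit with only the libraries of the contrast, the replicate number as a block, eBayes without the trend, each library left out in turn, and run lengths of 3 and 6. A covariate for library sets and a test on rows above 0 in all 18 libraries were added after the data were seen. In this design 3 libraries against 3 cannot give a permutation p below 0.1.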

Results

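Transcript levels were measured by RNA sequencing in Eubacterium limosum KIST612 growing on glucose, on CO or on H2/CO2, at mid-log and at early-stationary phase, with 3 libraries in each of the 6 groups. The study asked which genes differ in expression between the 3 carbon and energy sources and between the 2 growth phases. The deposited table gives RPKM for 4586 genes, of which 3662 had a mean of at least 5 RPKM and were tested. Genes are given by locus tag, because the table does not pair tags with names. Depth is unknown, since the table holds no counts. Rows listed above 0 in every library numbered 3340, and 180 were at 0 in all 18.

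Replicates of a group resembled one another more than libraries of other groups in most cases. Across the tested genes, the mean Pearson correlation of log2(RPKM + 1) between replicates lay between 0.927 in glucose at early-stationary phase and 0.950 in CO at mid-log. Between groups, glucose libraries correlated with gas-grown libraries at 0.729 to 0.804. CO libraries at early-stationary phase lay closest to H2/CO2 libraries at mid-log (mean r 0.9085), and CO libraries at mid-log lay closest to H2/CO2 libraries at early-stationary phase (0.888). Within a gas, the 2 phases correlated less, at 0.811 in CO and 0.824 in H2/CO2. The exception among replicates was replicate 3 of H2/CO2 at early-stationary phase. It correlated at 0.915 with the other replicates of its group and at 0.921 with the CO mid-log libraries.

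**Figure D1:**
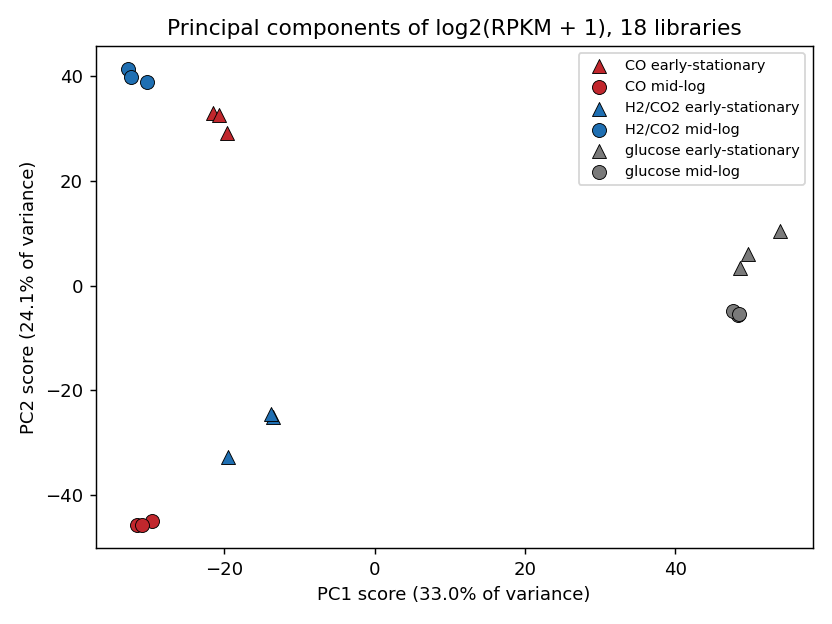
Scores of the 18 libraries on the first and second principal components of log2(RPKM + 1) over 3662 tested genes, which hold 33.04% and 24.1% of the variance; colour marks the substrate, circles mid-log and triangles early-stationary phase, and each point is 1 library. Glucose libraries lie apart on the first component, and the second places CO early-stationary beside H2/CO2 mid-log and CO mid-log beside H2/CO2 early-stationary.

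A few transcripts took a large part of the signal, and the more so in H2/CO2 at mid-log. The 10 most abundant genes of a library held 23.6% ± 0.113 of the summed RPKM in H2/CO2 at mid-log (SD, n = 3), against 13.0% ± 0.371 in glucose and 13.9% ± 0.488 in CO at mid-log. At early-stationary phase the corresponding shares were 19.0% ± 2.3 in glucose, 16.9% ± 0.426 in CO and 19.4% ± 3.21 in H2/CO2. One run of 10 neighbouring genes that includes ELI_3459 summed to 233676 ± 9675 RPKM in H2/CO2 at mid-log, which was 15.1% of the total, and to 6607 ± 902 RPKM or 0.619% in glucose at mid-log (SD, n = 3).

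CO against glucose at mid-log asks how the transcriptome differs when the gas is the carbon and energy source in place of the sugar. In CO, 644 genes were higher and 520 lower than in glucose. ELI_4182 was listed at 0 in all 6 glucose libraries, which is not taken here as measured absence, and stood at 201.6 ± 34.5 RPKM in CO at mid-log (SD, n = 3). A run of 14 neighbouring genes rose together, by 4.45 to 6.34 on the log2 scale. Its most abundant member, ELI_3909, stood at 20282 ± 2804 RPKM in CO and 262.5 ± 63.0 RPKM in glucose (log2 fold change 6.28, SE 0.261, limma adjusted p = 5.99e-13, n = 3 per group). The whole run summed to 31638 ± 3803 RPKM in CO against 527.4 ± 107.3 in glucose. Another run of 14 genes fell, with a median of -4.05 on the log2 scale, and it includes ELI_2759, the largest fall by the fixed rule, which stood at 1.93 ± 1.86 RPKM in CO and 230.0 ± 125.1 RPKM in glucose (log2 fold change -6.42, SE 0.918, limma adjusted p = 1.02e-05). ELI_0927 stood at 4.50 ± 1.93 RPKM in CO and 376.4 ± 15.8 RPKM in glucose (log2 fold change -6.15, SE 0.708, limma adjusted p = 6.39e-07). Other long runs that rose held 12, 10 and 9 genes, with medians of 1.62, 2.42 and 4.40, and the other long runs that fell held 9, 8 and 8 genes, with medians of -1.44, -3.11 and -4.44.

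Called genes made up 31.8% of those tested, and 279 rose and 260 fell by at least 4-fold. Of the called genes, 96.8% had 2 groups that did not overlap in any replicate, as did 50.9% of all tested genes, where chance gives 10%. The genes higher in CO held 37.5% ± 0.418 of the summed RPKM in CO and 9.49% ± 0.104 in glucose, and the genes lower in CO held 7.80% ± 0.0240 and 30.7% ± 0.264, shares computed, here and in the comparisons below, on the same libraries that selected the genes. Calls lay in 81 runs of at least 4 genes, which held 38.8% of them, while shuffled gene orders gave 4.15 runs on average and at most 13. Median-ratio scaling moved the log2 values of abundant genes in this contrast by 0.174 and gave 531 higher and 634 lower genes, so that which direction held more calls depends on the scaling.

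H2/CO2 against glucose at mid-log gave the most calls of the substrate comparisons, 810 genes higher and 681 lower in the gas. ELI_0072 rose from 3.80 ± 4.40 RPKM in glucose to 936.9 ± 153.3 RPKM in H2/CO2 (SD, n = 3 per group; log2 fold change 8.08, SE 0.526, limma adjusted p = 2.61e-10). The longest rising run held 11 genes with a median log2 fold change of 2.06, and its most abundant member, ELI_0422, stood at 250.9 ± 32.1 against 35.8 ± 8.40 RPKM (log2 fold change 2.79, SE 0.237, limma adjusted p = 1.17e-08). The other 3 long rising runs each held 10 genes, with medians of 2.07, 1.83 and 5.11, and the last of these is the run with ELI_3459. ELI_2759 was listed at 0 in all 3 H2/CO2 mid-log libraries, against 230.0 ± 125.1 RPKM in glucose. It belonged to a run of 16 genes that fell with a median of -4.95.

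The longest run of any comparison, 30 genes, fell in H2/CO2 at mid-log by 1.01 to 2.20 on the log2 scale (written as falls, median -1.52). It summed to 14501 ± 228.4 RPKM in H2/CO2 and 42126 ± 1624 in glucose (SD, n = 3). Its most abundant member, ELI_4036, stood at 641.0 ± 163.4 against 2936 ± 632.2 RPKM (log2 fold change -2.20, SE 0.268, limma adjusted p = 1.48e-06). Genes higher in H2/CO2 held 62.9% ± 0.405 of the summed RPKM there and 19.8% ± 0.360 in glucose. Calls made up 40.7% of the tested genes and 96.0% of them had non-overlapping groups, beside 56.0% of all tested genes and 10% by chance. They formed 91 runs, against a mean of 10.5 and a maximum of 22 in shuffled orders. Scaling by median ratios shifted abundant genes in this contrast by 0.157 on the log2 scale and gave 661 higher and 768 lower.

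Many genes differed from glucose in both gases in the same direction. At mid-log, 390 genes were higher and 212 lower in both gases than in glucose, and 106 were called in opposite directions. Independent lists of these sizes would share 142.4 and 96.7 genes. Both contrasts use the same 3 glucose libraries, and simulated groups with no change in either gas gave at most 1 gene called in the same direction in both. These simulations hold hardly any calls, so that count does not measure what sharing adds to lists of this size. The fold changes correlated at 0.560, beside 0.502 in the simulations, and their covariance was 1.40, beside 0.122 in the simulations, a difference of 1.28. At early-stationary phase 261 genes were higher and 228 lower in both gases, beside 67.4 and 69.9 for independent lists, and 38 were opposite. There the correlation was 0.616 beside 0.501 simulated, and the covariance 1.20 beside 0.122. With 3 glucose libraries per phase the controls could not be split into parts of at least 2, so part of the excess of these counts over independent lists may come from the shared libraries.

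A core of genes kept this gas response at both phases, which share no libraries. Of the 390 and 261 genes higher in both gases, 150 were the same genes, where independent lists would share 27.8. These 150 genes held 2.34% ± 0.127 of the summed RPKM in glucose and 13.8% ± 0.821 in CO and 19.7% ± 0.638 in H2/CO2 at mid-log, and 2.01% ± 0.168, 15.4% ± 1.06 and 11.8% ± 0.806 at early-stationary phase (SD, n = 3). Their median log2 fold changes lay between 1.95 and 2.22 in the 4 comparisons. Another 107 genes were lower in both gases at both phases, beside 13.2 for independent lists, and 48 of them lay in runs of at least 4 neighbours, the longest of 12 genes. Their share of the summed RPKM was 9.19% ± 1.21 in glucose at mid-log and 13.4% ± 1.53 at early-stationary phase. It was 2.16% ± 0.0589 in CO and 1.17% ± 0.0178 in H2/CO2 at mid-log, and 1.48% ± 0.138 and 4.27% ± 0.959 at early-stationary phase. The shares and fold changes of both sets of genes come from the same libraries that selected them, which fixed the direction of the fold changes.

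**Figure D2:**
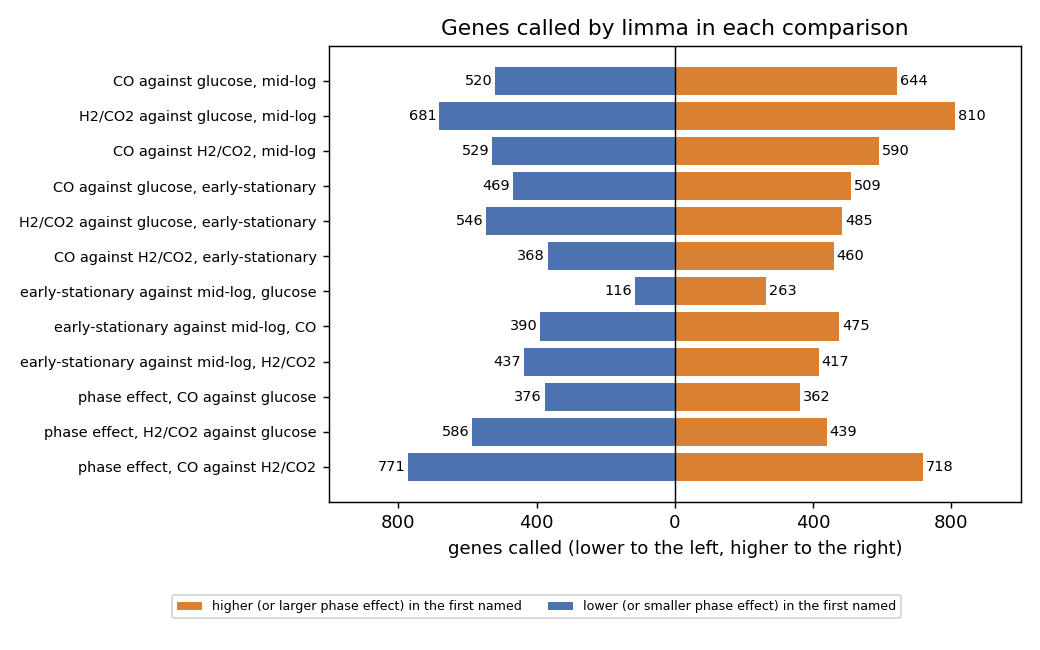
Number of genes called by limma (adjusted p below 0.05 and absolute log2 fold change of at least 1) in each of the 9 group comparisons and 3 tests of a difference between phase effects, out of 3662 tested genes, with genes higher in the first named group to the right and lower to the left. Glucose had the fewest phase calls (263 and 116), and the phase effect differed for 718 and 771 genes between CO and H2/CO2.

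CO against H2/CO2 at mid-log compares the 2 gaseous substrates directly. In CO, 590 genes were higher and 529 lower than in H2/CO2. The longest rising run held 16 genes with a median log2 fold change of 6.18, and ELI_3909 and ELI_3910 in it had the largest rises. ELI_3909 stood at 20282 ± 2804 RPKM in CO and 32.4 ± 12.9 RPKM in H2/CO2 (SD, n = 3 per group; log2 fold change 9.30, SE 0.261, limma adjusted p = 4.8e-16). ELI_3910 stood at 1479 ± 307.1 against 5.47 ± 9.38 RPKM (log2 fold change 9.09, SE 0.755, limma adjusted p = 4.93e-09). Other rising runs held 15, 11 and 10 genes, with medians of 1.98, 2.53 and 1.48. The longest falling run was the 10 genes with ELI_3459, which stood at 9786 ± 2609 RPKM in CO and 64487 ± 12190 RPKM in H2/CO2 (log2 fold change -2.74, SE 0.258, limma adjusted p = 2.9e-08). ELI_2726 fell from 269.3 ± 96.4 RPKM in H2/CO2 to 5.33 ± 2.82 RPKM in CO (log2 fold change -5.48, SE 0.401, limma adjusted p = 7.78e-10). Falling runs after the longest held 8, 7 and 7 genes, with medians of -1.72, -2.57 and -1.22.

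Calls between the gases at mid-log made up 30.6% of the tested genes, and 97.9% of them had non-overlapping groups, against 49.7% of all tested genes and 10% by chance. Genes higher in H2/CO2 held 51.2% ± 0.508 of the summed RPKM there and 15.3% ± 0.359 in CO (SD, n = 3). They formed, with the genes higher in CO, 67 runs, where shuffled orders gave at most 11. Set beside glucose as well, 190 genes were higher in CO than in both other substrates and 268 were higher in H2/CO2 than in both others. Lower than in both other substrates were 260 genes in CO and 326 in H2/CO2.

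Substrate comparisons at early-stationary phase gave 978 called genes for CO against glucose (509 higher, 469 lower), 1031 for H2/CO2 against glucose (485 and 546) and 828 for CO against H2/CO2 (460 and 368). ELI_4182 was again listed at 0 in glucose, and stood at 74.0 ± 36.7 RPKM in CO and 135.7 ± 53.2 RPKM in H2/CO2 (SD, n = 3). ELI_0927 had the largest fall in CO against glucose, 3.07 ± 0.808 against 1466 ± 333.9 RPKM (log2 fold change -8.49, SE 0.708, limma adjusted p = 1.25e-08). In H2/CO2 it stood at 137.7, 230.5 and 8.4 RPKM in replicates 1 to 3. ELI_4198 had the largest fall in H2/CO2 against glucose, 2.27 ± 1.36 against 230.8 ± 227.0 RPKM (log2 fold change -5.80, SE 0.835, limma adjusted p = 1.4e-05), with glucose replicates of 492.9, 99.5 and 100.1 RPKM. Between the gases, ELI_2264 stood at 312.4 ± 17.97 RPKM in CO and 5.47 ± 0.666 RPKM in H2/CO2 (log2 fold change 5.60, SE 0.288, limma adjusted p = 1.35e-11). ELI_2466 stood at 23.6 ± 3.12 RPKM in CO and 1547 ± 713.1 RPKM in H2/CO2 (log2 fold change -5.89, SE 0.303, limma adjusted p = 1.35e-11).

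The long runs at this phase were partly those of mid-log in other combinations. The 10 genes with ELI_3459 and 1 neighbour formed the longest rising run in CO against glucose, with a median of 4.05 and a sum of 150691 ± 14950 against 7510 ± 619.4 RPKM. The 14 genes with ELI_3909 formed the longest rising run in H2/CO2 against glucose, with a median of 2.72, and the longest falling run in CO against H2/CO2, with a median of -4.37. In CO they summed to 113.5 ± 15.2 RPKM, in H2/CO2 to 3123 ± 672.1 and in glucose to 551.5 ± 43.4 (SD, n = 3). Runs numbered 57, 52 and 49 in the 3 comparisons, against maxima of 8, 10 and 5 in shuffled orders. Without replicate 3 of H2/CO2, the library that lay near CO mid-log, the counts involving H2/CO2 were 1010 against glucose and 824 for CO against H2/CO2.

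By the labels as given, substrate effects against glucose carried over between phases, and the difference between the gases turned around. Across genes, the log2 fold changes at mid-log and early-stationary phase correlated at 0.482 for CO against glucose (95% interval 0.405 to 0.546) and at 0.416 for H2/CO2 against glucose (0.350 to 0.473). For CO against H2/CO2 the correlation was -0.571 (-0.627 to -0.513). Of the genes called in that comparison at both phases, 166 were higher in CO at mid-log and lower at early-stationary phase, and 297 went the other way. Independent lists would give 59.3 and 66.4. The same direction was kept by 17 genes higher in CO and 8 lower, where independent lists would give 74.1 and 53.2. Of the 190 genes that were highest in CO at mid-log, 102 were lower in CO than in H2/CO2 at early-stationary phase and 3 were higher. Of the 268 that were highest in H2/CO2 at mid-log, 148 were higher in CO than in H2/CO2 at early-stationary phase and 5 were lower.

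Early-stationary against mid-log phase within glucose asks what changes as growth on the sugar slows. It gave the fewest calls of the group comparisons, 263 genes higher and 116 lower at early-stationary phase, 10.3% of those tested. A run of 14 genes rose with log2 fold changes of 1.85 to 2.47 and summed to 34154 ± 1611 RPKM against 7539 ± 1078 at mid-log (SD, n = 3). Its most abundant member, ELI_4081, rose from 1186 ± 91.9 to 6285 ± 1384 RPKM (log2 fold change 2.38, SE 0.239, limma adjusted p = 7.94e-06). ELI_2036 was listed at 0 in all 3 mid-log libraries and stood at 73.2 ± 28.8 RPKM at early-stationary phase. The longest falling run held 7 genes, with a median of -1.57, and in it ELI_3604 fell from 4870 ± 716.6 to 1637 ± 228.4 RPKM (log2 fold change -1.57, SE 0.298, limma adjusted p = 0.00191). ELI_1617, the largest fall by the fixed rule, stood at 26.1, 85.2 and 76.6 RPKM at mid-log and 1.6, 23.4 and 1.1 RPKM at early-stationary phase (log2 fold change -3.47, SE 0.939, limma adjusted p = 0.0179). Its call was lost without glucose early-stationary replicate 1 or 3 (log2 fold change -2.98 and -2.83) and without glucose mid-log replicate 2 or 3 (-3.17 and -3.24), and also with a pseudocount of 0.1 (-3.94) and with only the libraries of the contrast (-3.47).

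Runs were few in glucose, 4 in all against a maximum of 2 in shuffled orders. Of the called genes 95.3% had non-overlapping groups, beside 29.4% of all tested genes and 10% by chance. Called genes that rose held 31.6% ± 0.568 of the summed RPKM at early-stationary phase and 15.5% ± 0.683 at mid-log. The balance of rises and falls depended on the scaling, since median-ratio scaling moved abundant genes in this contrast by 0.132 on the log2 scale and gave 193 higher and 170 lower genes, and quantile normalization gave 168 higher and 192 lower. Fitted with the 6 glucose libraries alone, limma called 157 higher and 53 lower.

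In CO, 475 genes rose and 390 fell from mid-log to early-stationary phase. The largest fall was that of ELI_3909, from 20282 ± 2804 to 23.4 ± 5.05 RPKM (SD, n = 3 per group; log2 fold change -9.71, SE 0.261, limma adjusted p = 2.06e-16), and all 14 genes of its run fell, with a median of -6.41. The longest falling run held 15 genes with a median of -2.28, and in it ELI_0775 fell from 527.7 ± 51.4 to 98.9 ± 20.6 RPKM (log2 fold change -2.42, SE 0.256, limma adjusted p = 1.82e-07). ELI_1958 rose from 6.63 ± 5.80 to 259.2 ± 24.5 RPKM (log2 fold change 5.35, SE 0.427, limma adjusted p = 3.26e-09). In the run of 10 genes with ELI_3459, that gene rose from 9786 ± 2609 to 46007 ± 6474 RPKM (log2 fold change 2.26, SE 0.258, limma adjusted p = 5.19e-07), and the run as a whole from 3.38% to 10.3% of the summed RPKM. Called genes formed 54 runs, against at most 5 in shuffled orders, and 99.2% of them had non-overlapping groups, against 46.2% of all tested genes and 10% by chance. Genes that rose held 40.7% ± 0.264 of the summed RPKM at early-stationary phase and 11.99% ± 0.531 at mid-log.

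In H2/CO2, 417 genes rose and 437 fell. The 10 genes with ELI_3459 formed the longest falling run, from 233676 ± 9675 to 16416 ± 2161 RPKM in sum (SD, n = 3), and ELI_3459 itself fell from 64487 ± 12190 to 3918 ± 1283 RPKM (log2 fold change -4.08, SE 0.258, limma adjusted p = 2.36e-10). ELI_0073 fell from 1231 ± 144.3 to 6.73 ± 6.21 RPKM (log2 fold change -7.59, SE 0.371, limma adjusted p = 4.16e-12). The longest rising run held 16 genes with a median of 3.27, and its most abundant member, ELI_2751, rose from 7964 ± 1008 to 33211 ± 13600 RPKM (log2 fold change 1.99, SE 0.282, limma adjusted p = 1.46e-05). ELI_2296 stood at 56.8, 0.5 and 0.0 RPKM at mid-log and at 520.4, 739.4 and 300.0 RPKM at early-stationary phase (log2 fold change 6.78, SE 1.09, limma adjusted p = 6.83e-05). The 14 genes with ELI_3909 rose with a median of 4.11. Runs numbered 43, against at most 7 in shuffled orders. Of the called genes 95.9% had non-overlapping groups, beside 41.3% of all tested genes and 10% by chance. Without replicate 3 at early-stationary phase the counts were 397 rises and 401 falls.

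**Figure D3:**
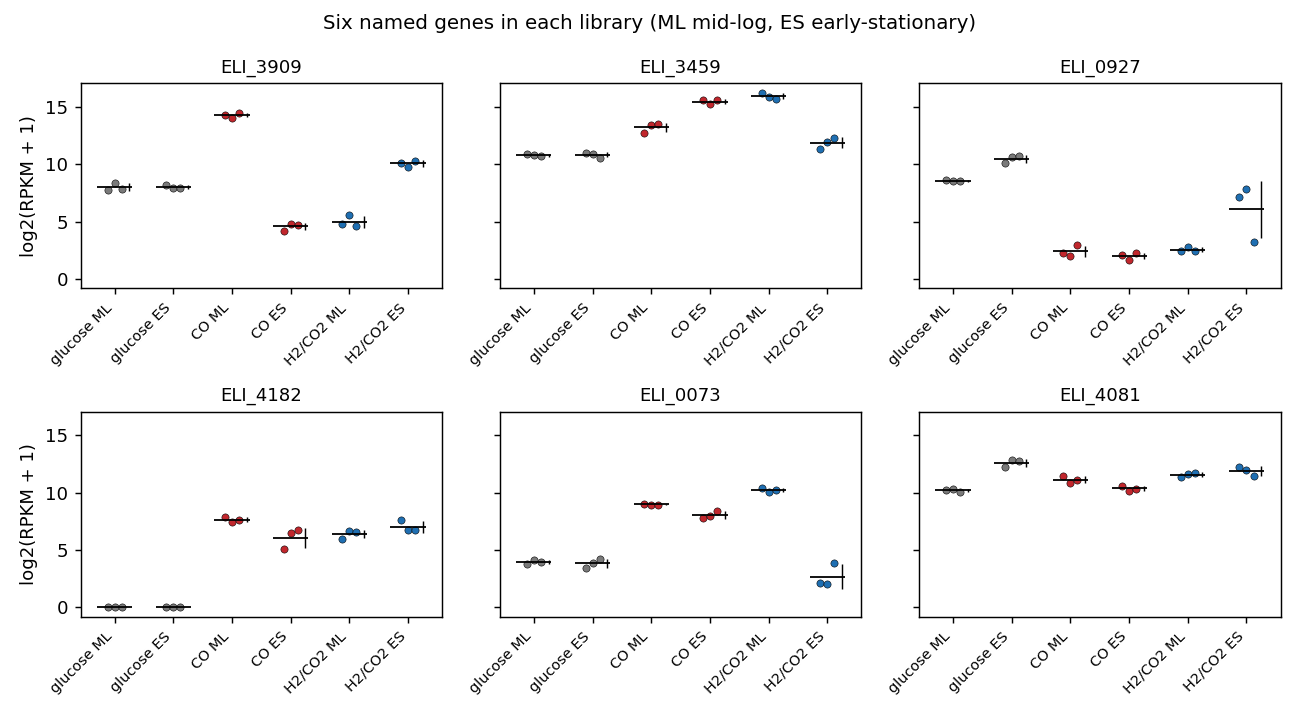
Values of 6 named genes in each of the 18 libraries on a log2(RPKM + 1) scale, with points for libraries, horizontal bars for the mean of 3 and vertical lines for 1 SD; ML is mid-log and ES early-stationary phase. ELI_3909 is highest in CO at mid-log, ELI_3459 in H2/CO2 at mid-log and CO at early-stationary phase, ELI_0073 in H2/CO2 at mid-log, ELI_0927 and ELI_4081 in glucose at early-stationary phase, and ELI_4182 is at 0 in the glucose libraries.

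The phase effect itself was tested for differences between substrates. It differed between CO and H2/CO2 for 1489 genes (718 more positive in CO, 771 more negative), which is 40.7% of those tested. It differed between H2/CO2 and glucose for 1025 genes (439 and 586) and between CO and glucose for 738 genes (362 and 376). The balance of directions against glucose depended on the scaling, as median-ratio scaling gave 543 more positive and 508 more negative in H2/CO2, and 417 and 335 in CO. Across genes, the phase effects of CO and H2/CO2 correlated at -0.632 (95% interval -0.698 to -0.559), and these contrasts share no library. Residuals of CO mid-log and H2/CO2 early-stationary libraries with the same number were correlated, and phase effects taken from single libraries with different numbers correlated at -0.463 on average over 6 pairs, beside -0.513 over 3 pairs with the same number. Of the genes called in both, 303 rose in CO and fell in H2/CO2 and 172 did the opposite, where independent lists would give 56.7 and 44.4. In both gases 3 genes rose and 8 fell. Glucose and CO phase effects correlated at 0.148 (0.110 to 0.191), and 107 genes rose in both, beside 34.1 for independent lists, while 7 fell in both, beside 12.4. Glucose and H2/CO2 phase effects correlated at -0.116 (-0.176 to -0.0611), or -0.0702 without H2/CO2 early-stationary replicate 3, and 95 genes that rose in glucose fell in H2/CO2, beside 31.4, while 16 did the opposite, beside 13.2. The counts shared with glucose depended on the scaling. For glucose and CO, median-ratio scaling gave 80 rising and 15 falling in both, beside 24.7 and 18.5. Quantile normalization gave 68 and 24, beside 21.6 and 22.2. For glucose and H2/CO2 the opposite counts were 69 and 32 with median-ratio scaling, beside 22.0 and 19.9. With quantile normalization they were 58 and 32, beside 21.01 and 20.45.

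**Figure D4:**
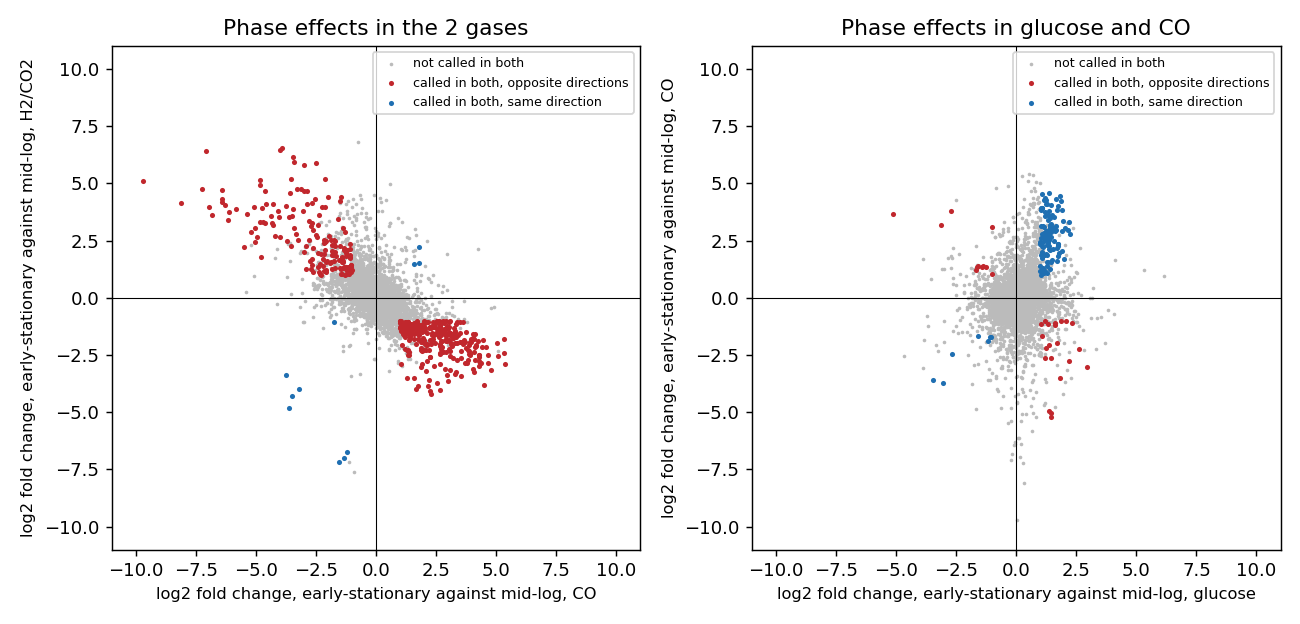
Log2 fold changes of early-stationary against mid-log phase for 3662 tested genes, CO (x axis) against H2/CO2 (y axis) at left and glucose against CO at right, with genes called in both contrasts coloured by whether their directions were equal. At left the genes called in both lie mostly in the quadrants of opposite sign (303 and 172 genes, with 3 and 8 in the others), and at right 107 genes rose in both.

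Along the gene order, the largest mean fall of neighbouring genes in CO lay around the run with ELI_3909. In the 101 consecutive tested genes with the lowest mean CO phase effect, the mean log2 fold change was -1.27 in CO, 0.69 in H2/CO2 and -0.02 in glucose. The lowest mean of any such window in 1000 shuffled orders was -0.71 for CO. Much of this came from the 14 genes of that run, since the 87 other genes had means of -0.38 in CO and 0.11 in H2/CO2. Among these 87, 12 fell and 6 rose in CO, while 9 rose and 14 fell in H2/CO2.

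**Figure D5:**
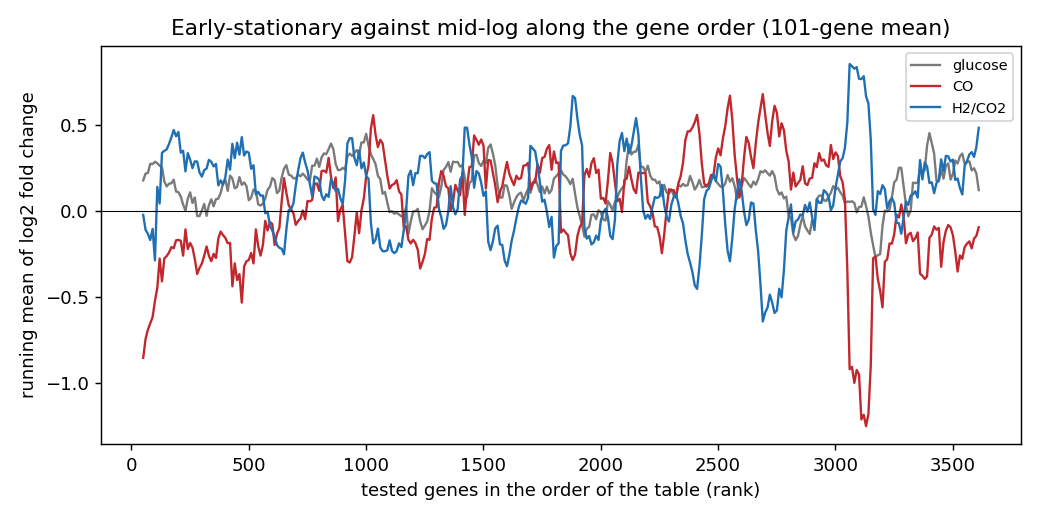
Running mean over 101 consecutive tested genes of the log2 fold change of early-stationary against mid-log phase (y axis) along the rank of the 3662 tested genes in the order of the table (x axis), with 1 line per substrate. The lowest CO mean of any window is -1.27, in a window that holds the 14 genes of the run with ELI_3909 and where the mean of H2/CO2 is 0.69.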

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

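The tests of a difference between phase effects were planned, and the tests of explanations and the relabellings in this part were chosen after the results were seen. The phase effect, early-stationary against mid-log, differed between CO and H2/CO2 for 1489 genes by limma's interaction contrast, between H2/CO2 and glucose for 1025 and between CO and glucose for 738. Substrates were relabelled among libraries within each phase, in 100 of the 200 possible ways with the real labelling among them. For CO against H2/CO2, 1 of the 100, the real one, gave as many as 1489 genes, the highest other being 807. For H2/CO2 against glucose 3 of the 100, the real one included, gave as many as 1025, the highest other being 1169. For CO against glucose 5 of the 100, the real one included, gave as many as 738, the highest other being 813. Relabellings that exchange most libraries of the substrates at 1 phase carry the substrate effect itself. These shares therefore do not measure chance for a difference in phase effect, and they do not exclude it for any of these tests.

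Named genes whose phase effect differed between substrates are given here by the fitted log2 difference, with the first substrate minus the second. For CO minus H2/CO2 it was -14.79 for ELI_3909, -13.48 for ELI_3910, -10.42 for ELI_2466, -7.54 for ELI_2296, -3.74 for ELI_0775 and -1.80 for ELI_2751, and it was 7.15 for ELI_2726, 7.13 for ELI_1958, 6.67 for ELI_0073, 6.34 for ELI_3459 and 2.43 for ELI_2264. For CO minus glucose it was -9.74 for ELI_3909, -5.18 for ELI_2036, -3.14 for ELI_4081 and -2.02 for ELI_0775, and 4.63 for ELI_1958, 2.97 for ELI_3604 and 2.24 for ELI_3459. For H2/CO2 minus glucose it was -8.29 for ELI_0072, -7.48 for ELI_0073, -7.25 for ELI_2036, -4.10 for ELI_3459 and -2.06 for ELI_4081, and 7.79 for ELI_2296, 5.88 for ELI_1617, 4.25 for ELI_2759 and 1.29 for ELI_4036. Between pseudocounts of 0.1 and 10, 14 of these 27 values moved by more than 1 and 0 changed sign. The largest move was for ELI_2036 in H2/CO2 minus glucose, from -10.63 to -3.73, and ELI_3910 in CO minus H2/CO2 went from -15.56 to -10.26. A group was listed at 0 in all its libraries for ELI_2036, ELI_1617 and ELI_2759.

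Phase effects of CO and H2/CO2 ran in opposite directions across genes (r -0.632), and CO early-stationary libraries resembled H2/CO2 mid-log libraries. Normalization between libraries and replicate 3 of H2/CO2 at early-stationary phase are argued against as the whole cause, since r was -0.6234 after quantile normalization and -0.5775 without that library. An exchange of the growth phases between the H2/CO2 mid-log and early-stationary libraries stays open as a candidate explanation, because the H2/CO2 phase effect as labelled correlated at -0.1159 with that of glucose while that of CO correlated at 0.148. The first of these values is weak evidence for it, since it was -0.0702 without H2/CO2 early-stationary replicate 3. From single libraries it averaged -0.0672 over 6 pairs of different sets (-0.133 to 0.00853), beside -0.0915 over 3 pairs of the same set. Over 6 pairs of different numbers it averaged -0.0529 (-0.144 to 0.00906), beside -0.107 over 3 pairs of the same number. Values from single libraries are not on the scale of those from group means. For glucose and CO the averages over different sets and numbers were 0.105 (0.0157 to 0.184) and 0.111 (0.0669 to 0.158). Summed RPKM rose from mid-log to early-stationary phase in glucose (1066120 ± 25347.8 to 1376610 ± 55043.4) and in CO (1122958 ± 14350.5 to 1458314 ± 32500.9). It fell in H2/CO2, from 1549505 ± 36240.3 to 1173313 ± 16122.7 (SD, n = 3), which goes with an exchange, though its cause was not tested. An exchange cannot be told apart from a phase effect that truly depends on the substrate, which the design names, so the labels were kept as given, and an exchange would change each H2/CO2 comparison at a named phase. Other exchanges of substrate or phase labels among the CO and H2/CO2 groups were not tested and are not excluded by these values.

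Replicate 3 of H2/CO2 at early-stationary phase lay between its group and CO mid-log, and its deviation from replicates 1 and 2 correlated across genes at 0.646 with the difference between CO mid-log and those replicates, beside 0.0768 to 0.285 for 12 libraries of other groups, since both terms share a reference, and at 0.422 and 0.493 with separate reference libraries, beside at most 0.0743 for the others. A mixture with RNA or reads of CO mid-log would give genes far higher in CO mid-log 1 common share, but 64.3% of 42 such genes lay outside 0.5 to 2 times the median share of 16.3%. An exchange with a CO mid-log library is argued against, since 0 of the CO mid-log libraries correlated better with replicates 1 and 2 than with their own group. An effect of the library set, a grouping of libraries found in the residuals, is argued against as the whole cause by a highest correlation of 0.0404 with that difference among the 5 other libraries of the set. CO mid-log replicate 3 among them gave -0.117, but its reference libraries enter both terms with opposite signs, which pulls the value below 0. That value therefore does not count against a set effect. Over all tested genes, deviations of the 5 other libraries of the set correlated with that of H2/CO2 early-stationary replicate 3 itself at 0.0156 to 0.173, the highest for CO mid-log replicate 3. That pair is among 9 pairs of libraries with the same set and number. Over the 1016 genes with a mean of at least 200 RPKM, residuals of these 9 pairs correlated at 0.561 on average and at least at 0.353. A shared part is therefore not excluded, and it was not small among abundant genes. A culture taken at another point of growth stays open and was not tested.

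Values fell along the gene order from the ends of the table to its middle in all 6 groups, with slopes of -0.334 and -0.330 in glucose and -0.264 and -0.484 in H2/CO2 at mid-log and early-stationary phase, and the fall was steepest in CO at mid-log, at -0.787 ± 0.0483 (SD, n = 3) against -0.147 ± 0.0317 at early-stationary phase. The slope of the CO phase effect, 0.640, was reached by 0% of 1000 shuffles of blocks of 50 genes and 0.2% with blocks of 200, while 6% of 200 rotations of the gene order gave a slope as large with the same sign (12% with either sign), those of the same sign lying within 5.5% of the table from the real order. Normalization between libraries and a single block of neighbouring genes are argued against as the whole cause, since the slope was 0.683 after quantile normalization and 0.557 without the 101 neighbouring genes of lowest mean. Gene dosage from ongoing replication, higher near an origin at the ends of the table, could give such a slope in CO, but the phase effects of the other substrates did not show it, with slopes of 0.00472 in glucose (95% interval -0.127 to 0.149) and -0.220 in H2/CO2 (-0.548 to 0.145). These values do not decide the question for CO, because growth rates and the position of the origin were not used here, and a response to CO of genes in these regions stays open and was not tested.

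For the 9 comparisons of 3 libraries with 3, the 10 splits are too few for a share below 0.05, and in each of them 1 split, the real one, gave as many genes as the real value. At mid-log the real values were 1164 for CO against glucose, 1491 for H2/CO2 against glucose and 1119 for CO against H2/CO2, and the highest other splits gave 0, 1 and 0 by limma. At early-stationary phase they were 978, 1031 and 828, with 1, 3 and 0 in the highest other splits. For the phase effects in glucose, CO and H2/CO2 they were 379, 865 and 854, with 3, 1 and 1. Every other split mixes libraries of both groups, so the real difference enters its spread and keeps its count low. The low counts of the other splits therefore do not measure chance.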

How the results depend on the processing

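In this part the library set covariate and the test on genes above 0 in all 18 libraries were chosen after the data were seen. All 12 counts of called genes stayed within 1.5 times their value under every alternative, with 1 exception. The phase effect in glucose gave 210 genes (157 higher, 53 lower) with only the libraries of the contrast, against 379, and 52% of the 379 were shared. That fit has fewer samples for its spread, but so have the fits of the other phase effects with only their own libraries. Those gave 950 genes in CO, against 865, and 840 in H2/CO2, against 854, which argues against fewer samples alone. The 379 rests on a spread taken over all 18 libraries, and the cause was not tested further. Ratios to the reported counts ran from 0.822 to 0.942 with a filter at 25 RPKM, from 0.831 to 1.04 with a pseudocount of 10, from 0.958 to 1.03 with median-ratio scaling, from 0.950 to 1.04 with quantile normalization, and from 0.741 to 1.06 with any 1 library left out. Without 1 library the glucose phase count ran from 281 to 382 and the CO against glucose count at mid-log from 1072 to 1138. As few as 63.3% of the reported calls of a contrast were shared with 1 library left out. Scaling between libraries changed which direction held more genes. Median-ratio scaling turned 644 higher and 520 lower into 531 and 634 for CO against glucose and 810 and 681 into 661 and 768 for H2/CO2 against glucose at mid-log, 509 and 469 into 480 and 495 for CO against glucose at early-stationary phase, and 417 and 437 into 429 and 418 for the H2/CO2 phase effect. It also turned the differences in phase effect from glucose, 362 and 376 into 417 and 335 for CO and 439 and 586 into 543 and 508 for H2/CO2. Quantile normalization turned the glucose phase effect from 263 and 116 to 168 and 192. Near-equal balances also turned under other settings, as for CO against H2/CO2 at mid-log, 515 and 533 with genes above 0 in all 18 libraries.

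With the replicate number as a block (replicate block), the counts were 1141, 1478 and 1099 for CO against glucose, H2/CO2 against glucose and CO against H2/CO2 at mid-log, 960, 1011 and 819 at early-stationary phase, 348, 845 and 829 for the phase effects of glucose, CO and H2/CO2, and 696, 959 and 1431 for the differences in phase effect of CO from glucose, H2/CO2 from glucose and CO from H2/CO2. Replicate numbers did not pair the groups of the 9 group comparisons, where residuals of libraries with the same number correlated below 0 at each number. Such residuals correlated above 0.1 at all 3 numbers in 1 of 15 pairs of groups, CO mid-log with H2/CO2 early-stationary (0.202, 0.179 and 0.173). They were also above 0 at each number for glucose mid-log with CO early-stationary (0.118, 0.0909 and 0.147). The same held for glucose early-stationary with H2/CO2 mid-log (0.11, 0.115 and 0.091). CO mid-log and H2/CO2 early-stationary enter the difference in phase effect between CO and H2/CO2, and are also compared with one another below without pairing. The other pairs enter the differences in phase effect of CO from glucose and of H2/CO2 from glucose.

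Of 499 values of named genes under alternatives, 493 kept their direction and call, and 6 lost the call with their direction kept, all of ELI_1617 in the glucose phase effect. The named genes were picked for large changes or abundance in these same libraries, so this count says little about called genes in general. Sizes depended on the pseudocount, and 17 of 30 values moved by more than 1 between 0.1 and 10, as for ELI_3910 (11.05 and 6.73, CO against H2/CO2 at mid-log), ELI_0072 (8.93 and 6.13, H2/CO2 against glucose at mid-log) and ELI_2296 (8.34 and 4.70, H2/CO2 phase effect). Run counts depended on the length asked for: CO against glucose at mid-log had 124 runs of at least 3 genes, 81 of at least 4 and 30 of at least 6. The gene list tests and the alternative with an estimated correlation were not run, for want of names. Depth is unknown, so what it limits could not be assessed.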

Other observations

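The choice of what is described in this part was made after the data were seen, and so was the search for library sets. Further runs of neighbouring genes moved together. A run of 9 genes with ELI_2466 rose in H2/CO2 from mid-log to early-stationary phase, from 224.0 ± 67.3 to 11140 ± 2172 RPKM in sum (SD, n = 3; median log2 fold change 5.79), and stood at 381.7 ± 27.8 RPKM in CO at early-stationary phase. A run of 9 genes with ELI_3604 was higher in CO at early-stationary phase, at 60002 ± 2442 RPKM, than in H2/CO2 (12405 ± 4960) or glucose (8009 ± 337.7).

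Some genes set 1 group apart from its neighbours, which are the other substrates at the same phase and the same substrate at the other phase. In CO at mid-log 246 genes were lower than in all 3 neighbouring groups and held 2.56% ± 0.0396 of the summed RPKM, against 15.9% ± 0.297 in CO at early-stationary phase (SD, n = 3). In H2/CO2 at mid-log 196 genes were higher than in the 3 neighbouring groups and held 34.9% ± 0.169, against 8.18% ± 0.193 in H2/CO2 at early-stationary phase and 28.5% ± 0.886 in CO at early-stationary phase. Glucose had 26 such genes at mid-log and 54 at early-stationary phase. The shares were computed on the same libraries that selected the genes.

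Across phases and substrates, limma called 272 genes between CO early-stationary and H2/CO2 mid-log libraries (168 higher, 104 lower) and 433 between CO mid-log and H2/CO2 early-stationary libraries (185 and 248). Each count is below those between the phases of either gas.

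Residuals of the libraries from their group means fell into 3 sets of 6 libraries, each with 1 library of each group. Of 7776 arrangements the same one had the highest mean correlation within sets in each of 4 strata of abundance, with means of 0.0345, 0.176, 0.275 and 0.386. The second best gave 0.0326, 0.14, 0.213 and 0.296, so the lowest stratum hardly told them apart. Over the 1016 genes with a mean of at least 200 RPKM, 9 pairs with the same set and number had a mean residual correlation of 0.561. For the remaining pairs within sets it was 0.23. Over all tested genes the arrangement by replicate number ranked 7776th. With the set as a covariate the count for CO against glucose at mid-log was 1183, and ratios to the 12 reported counts ran from 1.01 to 1.17. The sets were chosen for high residual correlation in these same libraries. That choice raises the correlations within sets, and a covariate built on it takes up residual spread. These counts therefore do not test whether the calls depend on the sets. Within the sets, the phase effects of CO and H2/CO2 correlated across genes at -0.471, -0.569 and -0.496.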
